A study of Rattus norvegicus with 15 samples.

How the data were processed

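RNA was measured by sequencing of brain tissue from Sprague-Dawley rats taken 72 h after modelling. Per the labels, the tissue came from the brain with basal ganglia as the cell source, total RNA was extracted with a column kit that separates DNA and RNA, and all samples carried 1 batch date. The design named 3 groups of 5 rats each: sham operation, intracerebral hemorrhage (ICH), and ICH with mithramycin A (ICH_MA). The labels described 15 samples, and the table held columns for 11 of them: 5 sham, 3 ICH (replicates 1, 2 and 5) and 3 ICH_MA (replicates 1, 2 and 3). The other 4 labelled samples were not analysed here, and how the 11 were chosen is not given in the sources used here. Columns were matched to samples by the library name in the labels.

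The deposited table held whole-number counts per gene, without normalization, for 15094 genes named by Ensembl rat gene IDs. Per the submitters' processing notes, the tools were Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 with the genome build mRatBN7.2. Their roles, the annotation release, the use of strand and any filter on low counts are not given in the sources used here. RSEM gives estimated counts, and whether the authors rounded them is not given either. A total of 14618 genes had at least 10 counts in every library and the lowest total of any gene over the 11 libraries was 20, so very rare transcripts were not analysed here. Reads shared between near-identical gene copies, overlapping genes or antisense partners could be divided between IDs by the counting.

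The files do not pair the IDs with gene names. The reference gene table used here held 47357 genes without Ensembl IDs, and 0 of the 15094 IDs matched a symbol. The 33 gene lists fixed before the data were examined (17 of processes, among them 19 cuproptosis genes, and 16 of cell types) hold symbols and could not be tested. The counts of changed and reversed cuproptosis genes, the set tests, pathway enrichment and every check of cell composition were therefore left out. Results are given as counts of genes, fold changes, shares of counts and positions of libraries, with 4 genes given by ID.

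Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which kept 14963 genes and removed 131. Counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3, with all 11 libraries in 1 quasi-likelihood model with a mean per group. Each of the 3 comparisons was tested with edgeR's quasi-likelihood F test, and p-values were adjusted by Benjamini and Hochberg over the genes tested. Genes with an adjusted p under 0.05 were called changed. A reversed gene was one changed in ICH against sham and in ICH_MA against ICH in opposite directions. Standard errors of log2 fold changes came from the same test. CPM values, counts scaled to a common library total, used TMM-scaled totals, and log2 CPM used a prior count of 2. The design had assumed all 15 libraries, and the same model was fitted to the 11.

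ICH_MA and sham were each compared with the same 3 ICH libraries, so chance values are shared between comparisons. Groups were simulated from the real means, spreads and library sizes in 10 draws with no group differing and in 10 draws with sham differing and ICH_MA equal to ICH. Each simulated gene varied independently, with the same spread in all groups. The planned split of the ICH libraries into separate parts needs at least 2 libraries in each part and could not be made with 3.

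Named genes were chosen by part of a rule fixed before the data were examined. It took the largest rises and falls by log2 fold change. These needed adjusted p under 0.05, a mean of at least 1 CPM and complete separation of the groups. The rule was also limited to genes with names, which could not be applied here. A total of 1834 rises and 1146 falls met the other criteria in ICH against sham. The text was held to 2 rises and 2 falls because the IDs have no names. The same 4 genes are given in the other comparisons, where no separate choice of genes was made.

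The position of a library between sham and ICH, chosen after the data were examined, was the projection of its log2 CPM on the axis from the sham mean (0) to the ICH mean (1), over genes changed between them. For a sham or ICH library, the genes and the axis were found without it. An ICH_MA library was given its mean over the axes that leave out 1 ICH library each. Held-out positions therefore lie on different axes. To compare ICH_MA with ICH, all libraries were also placed on 1 axis from the sham mean (0) to the mean of the 6 ICH and ICH_MA libraries (1), over the 2895 genes changed between sham and these 6 taken as 1 group. Positions were compared with exact two-sided permutation tests.

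The tests were tested on simulated counts with 200 changed genes, drawn independently with the same spread per gene in all groups. The spread per gene was edgeR's own estimate from the real counts, which may favour edgeR. edgeR recovered 83% of them in the simulated ICH against sham comparison, 84% in ICH_MA against ICH and 86.5% in ICH_MA against sham. For 1.5-fold changes it recovered 46%, 60% and 62%, and for 2-fold changes 90%, 84% and 88%. False calls were 7 of 173, 9 of 177 and 10 of 183. DESeq2 1.42.0 gave 44 false calls of 223, 44 of 221 and 42 of 227.

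Alternatives fixed before the data were examined were DESeq2, limma-voom with sample quality weights (limma 3.58.1), RLE scaling, no filter on low counts, only the groups compared in the model, the replicate number as a block, an added log2 fold change of at least 1, and leaving out each library. DESeq2 without ICH replicate 5 was added after the data were seen.

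Library totals ranged from 56393423 to 67733469 counts. No pair of libraries of a group was alike within sampling noise, with a lowest chi-square per degree of freedom of 16.9. The study design describes separate rats, so the spread between libraries includes that between animals. Floors for a count of 0 were set at 3 counts over the group and cover counting error only.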

Results

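Gene expression was measured by RNA sequencing in brain tissue of rats 72 h after modelling of intracerebral hemorrhage (ICH), bleeding into the brain, or after a sham operation. A further group received mithramycin A (ICH_MA), a DNA-binding drug known to block binding of the transcription factor Sp1 to GC-rich DNA. The libraries analysed comprised 5 sham, 3 ICH and 3 ICH_MA, and 4 further labelled samples were not analysed here. Totals were 56393423 to 67733469 counts per library in sham, 58317912 to 65438000 in ICH and 57164791 to 66381416 in ICH_MA. Each library had counts for 15021 to 15068 of the 15094 genes, and the 10 highest genes took 8.749% to 10.17% of its counts. Genes are given by Ensembl ID because the files do not pair IDs with names.

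The first comparison asked which genes changed with hemorrhage. In ICH brain, 2250 genes rose and 1412 fell, together 24.5% of the 14963 genes tested (edgeR quasi-likelihood F test, adjusted p under 0.05, 3 ICH against 5 sham libraries). Rises made up 61.4% of the changed genes, against 53.5% with DESeq2. With edgeR they made up 53.9% without Sham replicate 1 and 69.5% without ICH replicate 1. Rises were larger than falls in size. The median log2 fold change was 0.68 among the genes that rose and −0.34 among those that fell, with a median SE of 0.11 over the changed genes. A total of 745 genes rose at least 2-fold and 57 fell at least 2-fold, and 275 rose and 5 fell at least 4-fold. The genes that rose took 7.68% ± 0.23 of all counts in sham (SD, n = 5) and 11.7% ± 1.7 in ICH (SD, n = 3). Those that rose at least 2-fold took 0.51% ± 0.018 in sham and 1.79% ± 0.65 in ICH. The genes that fell took 20.9% ± 0.9 of counts in sham and 17.2% ± 0.88 in ICH. These shares describe genes chosen by the same libraries. Complete separation of the groups was seen in 26% of the genes tested, where chance gives 3.57%, and 3039 of the changed genes were separated.

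ENSRNOG00000065254 had 0 counts in all 5 sham libraries and 189 to 279 counts in the ICH libraries. Its level in ICH was 3.97 ± 0.964 CPM (SD, n = 3), at least 414-fold higher than the sham floor of 0.00959 CPM set by 3 counts over the group (edgeR adjusted p = 0.0096). The call was lost in 1 of 15 alternatives, where adjusted p ranged from 3.99e-05 to 0.0707. ENSRNOG00000007178 rose from 0.0274 ± 0.0411 CPM in sham (SD, n = 5) to 4.95 ± 3.96 CPM in ICH (SD, n = 3), a log2 fold change of 7.34 with SE 0.99 (edgeR adjusted p = 0.000679). Its ICH libraries differed widely, with 543, 274 and 79 counts in replicates 1, 2 and 5, and its sham level rested on 9 counts in all. ENSRNOG00000020009 fell from 14.1 ± 6.88 CPM in sham to 2.79 ± 2.08 CPM in ICH, a log2 fold change of −2.32 with SE 0.58 (edgeR adjusted p = 0.0144). Without ICH replicate 1 its log2 fold change was −2.31 (edgeR adjusted p = 0.0595). ENSRNOG00000017302 was at 6.03 ± 7.84 CPM in sham and 0.0664 ± 0.115 CPM in ICH, a log2 fold change of −6.49 with SE 2.03 (edgeR adjusted p = 0.0383). Its sham libraries held 20 to 1105 counts, 1 ICH library held 12 counts and the other two held 0. This call was lost in 8 of 15 alternatives, where adjusted p ranged from 0.0225 to 0.293 and the log2 fold change from −11.56 to −2.87. The former came without ICH replicate 2, which leaves ICH libraries at 0 counts, so that the fitted fold depends on the prior count.

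The ICH libraries lay at different distances from sham. Genes that rose took 12.8% and 12.6% of counts in ICH replicates 1 and 2 and 9.72% in replicate 5. Each ICH library was placed on its own axis from sham (0) to the other ICH libraries (1), and the held-out positions of ICH replicates 1, 2 and 5 were 1.272, 1.106 and 0.478. The number of changed genes was 1992 without ICH replicate 1, 2231 without replicate 2 and 4484 without replicate 5.

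**Figure D1:**
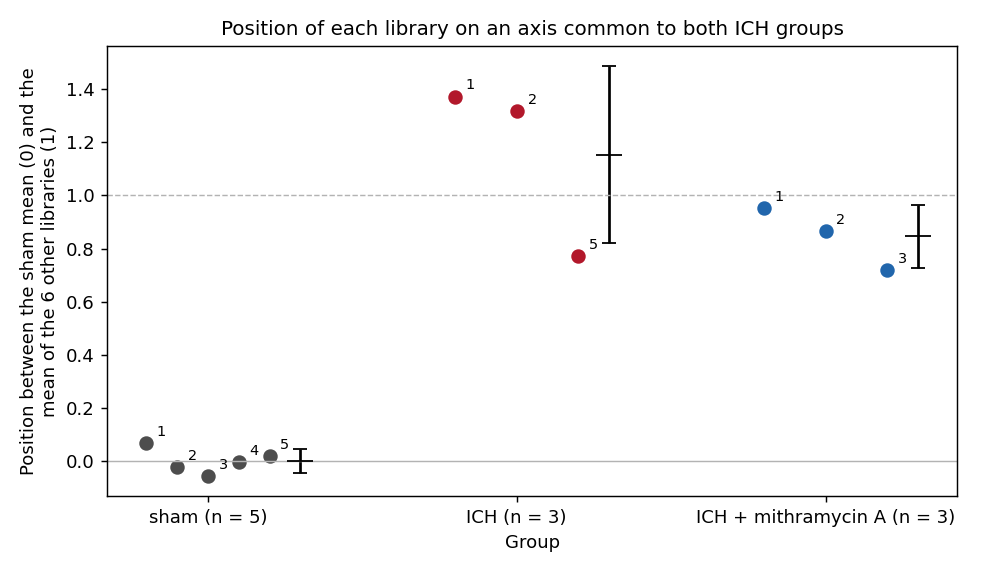
Position of each library (points, numbered by replicate) on the axis from the sham mean (0) to the mean of the 6 ICH and ICH_MA libraries (1), without units, by group. Black bars give the mean and SD, and ICH replicate 5 at 0.771 lies among the ICH_MA libraries at 0.72 to 0.953.

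The second comparison asked what mithramycin A changed after hemorrhage. No gene passed the threshold between ICH_MA and ICH with edgeR (0 of 14963, smallest adjusted p = 0.176, 3 against 3 libraries). At an unadjusted p under 0.05 there were 2318 genes, 932 higher and 1386 lower in ICH_MA, where chance gives 748. DESeq2 called 476 genes, 194 higher and 282 lower, and limma-voom called 0. Complete separation was seen in 17% of the genes, where chance gives 10%. The median SE of a log2 fold change was 0.12. In simulated data with the same numbers of libraries, edgeR recovered 84% of genes with 2-fold changes in this comparison. The simulation gave all groups the same spread, whereas the real ICH libraries differed more. The SD of held-out positions, which lie on different axes, was 0.419 in ICH, 0.066 in sham and 0.093 in ICH_MA. On the single axis common to ICH and ICH_MA, the SD was 0.332 in ICH, 0.046 in sham and 0.118 in ICH_MA. Recovery in the real data may therefore be lower, and 0 calls do not exclude 2-fold changes.

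One ICH library changed this count. Without ICH replicate 5, edgeR called 1137 genes, 286 higher and 851 lower in ICH_MA than in ICH. Leaving out any other ICH or ICH_MA library gave 0 genes. On an axis from sham (0) to the mean of the 6 ICH and ICH_MA libraries (1), which treats both groups alike, positions were 1.154 ± 0.332 in ICH (SD, n = 3) and 0.846 ± 0.118 in ICH_MA (SD, n = 3). The difference did not pass an exact two-sided permutation test (p = 0.3, smallest possible 0.1).

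The design also screened for genes whose change with hemorrhage turned back under the drug. The number of such reversed genes was 0 with edgeR, 0 with limma-voom and 377 with DESeq2. Of the DESeq2 genes, 243 had risen and 134 had fallen with hemorrhage. Without ICH replicate 5, edgeR gave 1067 reversed genes, 820 risen and 247 fallen with hemorrhage. Among the 3662 genes changed in ICH, 3397 (92.8%) had an ICH_MA mean on the sham side of the ICH mean. For the genes that rose it was 2099 of 2250 (93.3%), and for those that fell 1298 of 1412 (91.9%). Because both comparisons use the same ICH libraries, this direction is favoured by chance, and simulated data with ICH_MA equal to ICH gave 63.1% (62% to 64.4% over 10 draws). Simulated genes varied independently and with the same spread in all groups. Genes of a real library move together and the real ICH libraries differed more, so the draws are not a full measure of chance. Across genes, log2 fold changes of ICH against sham and of ICH_MA against ICH had Pearson's r = −0.658, Spearman's rho = −0.689 and a covariance of −0.155. Simulated groups without any difference gave r = −0.55 (−0.626 to −0.473) and a covariance of −0.035. With sham differing and ICH_MA equal to ICH they gave r = −0.225 and a covariance of −0.0401. Genes are not independent replicates, and part or all of the excess may come from the shared ICH libraries, which were too few to split.

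**Figure D2:**
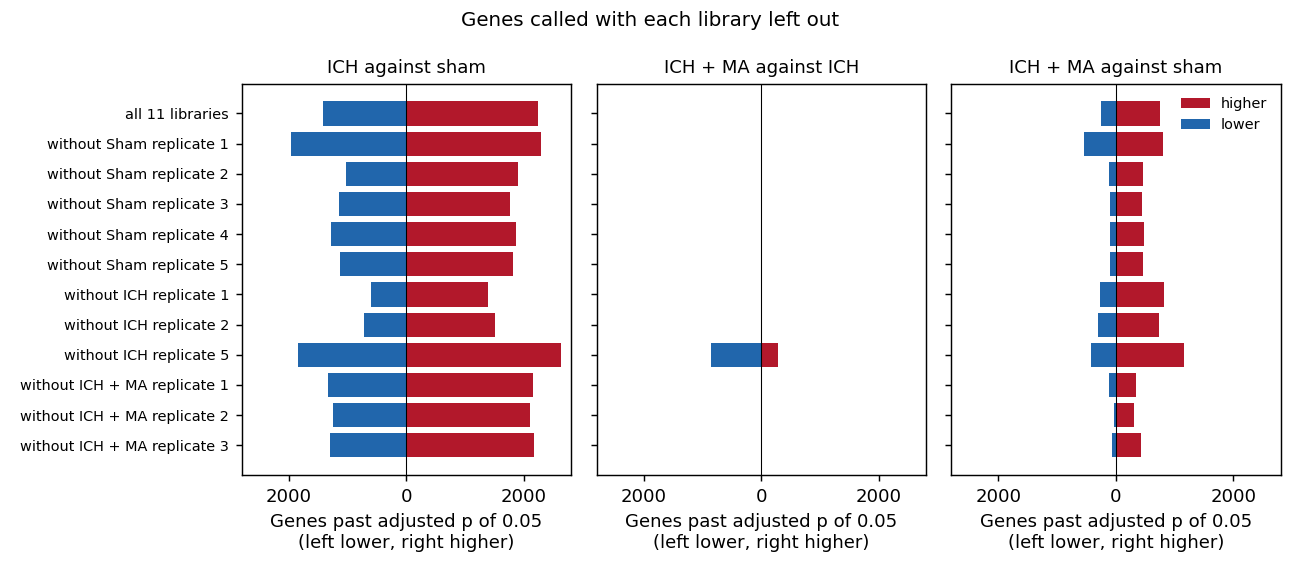
Number of genes past an adjusted p of 0.05 (edgeR), higher to the right and lower to the left, with all 11 libraries and with each library left out in turn, in each comparison. In ICH_MA against ICH the count is 0 with all libraries and 1137 without ICH replicate 5.

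The third comparison asked how treated rats differed from sham. In ICH_MA brain, 748 genes rose and 250 fell against sham, 6.67% of the genes tested (edgeR, adjusted p under 0.05, 3 against 5 libraries). The median log2 fold change was 0.86 among the genes that rose and −0.36 among those that fell, with a median SE of 0.14. A total of 326 genes rose and 8 fell at least 2-fold. Complete separation held for 19% of the genes, where chance gives 3.57%. The genes that rose in ICH took 9.82% ± 0.086 of counts in ICH_MA (SD, n = 3), and those that fell took 18.8% ± 0.43. Among genes that rose in ICH, the median log2 fold change against sham was 0.68 in ICH and 0.35 in ICH_MA. Among those that fell it was −0.34 and −0.18. These genes were chosen by the ICH libraries, which favours larger ICH medians even without an effect of the drug. The number of changed genes was 1823 with DESeq2 (61.9% higher, against 74.9% with edgeR), 2104 with limma-voom and 1541 with only these groups in the model. It was 459, 348 and 506 without ICH_MA replicates 1, 2 and 3, and 570, 545, 577 and 569 without Sham replicates 2, 3, 4 and 5. Without Sham replicate 1 it was 1338, with 798 higher and 540 lower. Without ICH replicate 5, a library outside the groups compared, it was 1575. The model shares the spread per gene over all groups, so ICH libraries bear on this count. With only the groups compared in the model, ICH against sham gave 3125 genes, against 3662 with all groups.

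Of the 748 genes that rose in ICH_MA, 660 (88.2%) also rose in ICH, where independent lists would share 112. Of the 250 that fell, 185 (74%) also fell in ICH, where independent lists would share 23.6. No gene was called in opposite directions (0, against 108 for independent lists). Both comparisons use the same sham libraries, and simulated groups without any difference had 0 calls to share, so they give no measure of this overlap. With sham differing and ICH_MA equal to ICH, simulated groups shared 1760 rises and 1110 falls. Across genes the log2 fold changes against sham had Pearson's r = 0.811 and a covariance of 0.246, against 0.367 and 0.0209 in simulated groups without any difference, and 0.921 and 0.408 with ICH_MA equal to ICH. The observed values lay between the simulated ones. Simulated groups shared the sham libraries in the same way, so their values include this sharing. Their genes varied independently, so the draws are not a full measure of chance.

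**Figure D3:**
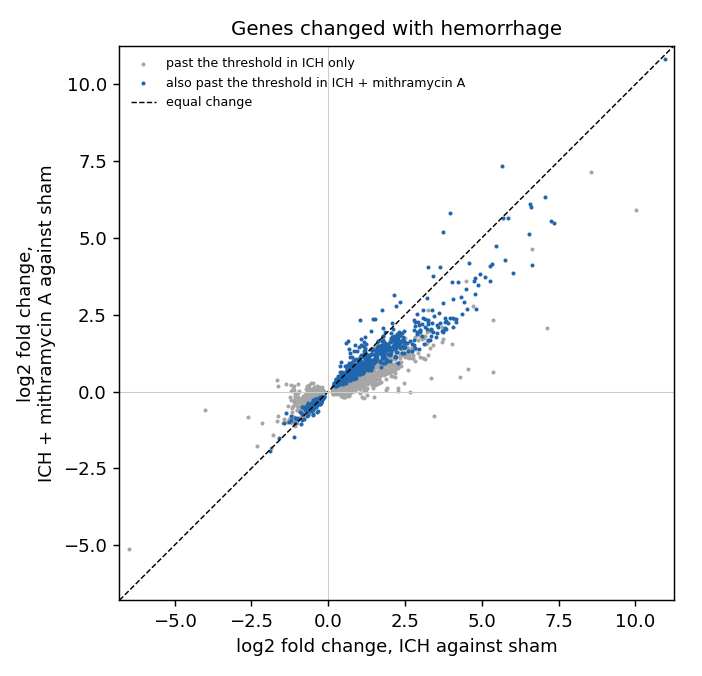
Log2 fold change against sham in ICH (horizontal) and in ICH_MA (vertical) for the 3662 genes changed in ICH, each point a gene, with the line of equal change. Blue points also passed the threshold in ICH_MA, and 3397 genes had a smaller rise or fall, or a change of sign, in ICH_MA.

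Of the named genes, ENSRNOG00000065254 had 0, 408 and 248 counts in ICH_MA replicates 1, 2 and 3. Its mean of 3.6 ± 3.58 CPM (SD, n = 3) was at least 375-fold higher than the sham floor (edgeR adjusted p = 0.028), a call lost in 8 of 14 alternatives, where adjusted p ranged from 0.000161 to 0.267. Against ICH its log2 fold change was −0.14 with SE 1.19 (edgeR adjusted p = 0.973). ENSRNOG00000007178 was at 1.36 ± 1.12 CPM in ICH_MA, a log2 fold change against sham of 5.48 with SE 1 (edgeR adjusted p = 0.01). Against ICH its log2 fold change was −1.86 with SE 0.83, which did not pass (edgeR adjusted p = 0.315). ENSRNOG00000020009 was at 4.15 ± 1.46 CPM in ICH_MA, with log2 fold changes of −1.76 against sham (edgeR adjusted p = 0.0872) and 0.57 against ICH (adjusted p = 0.686). DESeq2 put the former past the threshold (adjusted p = 0.0354, range over the alternatives 0.0152 to 0.274). ENSRNOG00000017302 was at 0.162 ± 0.28 CPM in ICH_MA, and its log2 fold changes of −5.13 against sham (edgeR adjusted p = 0.117) and 1.36 against ICH (adjusted p = 0.828) did not pass.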

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

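The tests of a swap with an ICH_MA library, of 1 ICH library behind the correlation, of the assignments of labels, and of the positions of the groups were chosen after the results were seen. Sham replicate 1 stood apart from the other sham libraries in 2 of 14 measures. Its mean Spearman correlation with the other sham libraries was 0.9887, against 0.9923 to 0.9932 for the others, a gap of 0.8 of the range where 0.71 is the critical ratio for 5 values. The share of its counts in genes that fell with hemorrhage was 19.3%, against 21% to 21.6%, a gap of 0.739 of the range. For a single measure chance marks about 1 in 20 groups, so over 14 measures, which were not independent, chance marks are more frequent than that. Its held-out position was 0.154, against −0.022 to 0.034 for the others.

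ICH replicate 5 lay nearer to sham than the other ICH libraries, at a held-out position of 0.478 against 1.272 and 1.106. Its total of 65438000 counts lay within the range of the sham libraries (56393423 to 67733469). Thinning all libraries to the lowest total left the position at 0.478. A bound set beforehand took a position that stayed this low as going against depth as the cause. The position stayed with totals made equal, which argues against a difference in total counts and covers nothing else. A swap with an analysed ICH_MA library would need one of them near the other ICH libraries, and on the axis to ICH replicates 1 and 2 they lay at 0.581, 0.515 and 0.421. A weaker form of the same response may explain it: over genes called without it, its fold changes correlated with those of the other ICH libraries at 0.801 across genes (0.744 to 0.833 over 10 choices of sham reference), with a slope of 0.472. A smaller hematoma, a different piece of tissue, a swap with a sample not analysed here or a single wrong label stay open and were not tested.

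Fold changes of ICH_MA against ICH ran opposite to those of ICH against sham. The covariance beyond that expected from the spread of the ICH libraries alone was −0.0954 on the log2 CPM scale, and −0.1937 without ICH replicate 5 to −0.029 without ICH replicate 1. A bound set beforehand would have excluded the shared ICH libraries as the cause because every one of these values was below 0, but it was judged wrong after the result was seen, since genes of a library move together and 2 of the 20 assignments of the 6 labels, the real one included, gave an excess as negative (the other −0.117). Shared ICH libraries and an effect of the drug therefore cannot be told apart with 6 libraries. A part played by 1 ICH library stays open. The correlation was −0.612 without ICH replicate 1, and −0.593 and −0.561 without ICH_MA replicates 2 and 3. Chance values of the correlation differ with the numbers of libraries left, so these values do not decide. The covariance beyond expectation was −0.029 without ICH replicate 1 and −0.0627 without ICH replicate 2. Without ICH_MA replicates 2 and 3 it was −0.0974 and −0.0811, nearer to the −0.0954 with all libraries.

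ICH_MA lay between sham and ICH. A drug that scales the whole response may account for this: at the fitted point of 0.6561 of the way from sham to ICH (0.5209 to 0.8519 with 1 library left out), 0.0134% of the genes departed from it (2 of 14963), and without ICH replicate 5 at its own point 0.133% did. In simulated data this test recovered 89% of 200 genes moved off the point 2-fold, and smaller departures were not tried. From a point of 1, which is no effect of the drug, 0 of 14963 genes departed with all libraries. Few departures therefore do not single out the fitted point. Without ICH replicate 5, 1137 genes (7.59%) departed from a point of 1. This library lay among the ICH_MA libraries, so leaving it out widens the gap between the groups. DESeq2 called 476 genes in ICH_MA against ICH with all libraries. In simulated data 44 of its 221 calls were false, more than with edgeR. Those counts were drawn with edgeR's own estimates of spread, which may favour edgeR. The count thus rests on this library and on the tool, and does not exclude a point of 1. A lower position of ICH_MA on an axis common to both groups gave an exact two-sided permutation p of 0.3 with 3 against 3 libraries, and held-out positions, which lie on different axes, gave an exact permutation p of 0.4, so neither decides. A difference in lesion size between the rats stays open, with no such measure used here.

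For ICH against sham, 1 of 56 splits of the libraries, the real one, gave as many changed genes (3662, highest other 158). For ICH_MA against sham 1 of 56 did, again the real one (998, highest other 169). This is the smallest share that 56 splits can give. It speaks against an arbitrary grouping of these libraries. It does not cover a bias from how the 11 libraries were chosen, which is not given. For ICH_MA against ICH and for reversed genes, all 10 of 10 splits gave at least the real count of 0 (highest other 1 in each), and 10 splits are too few for a share under 0.05.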

How the results depend on the processing

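DESeq2 without ICH replicate 5 was chosen after seeing the data. Over the 5 main results, 57 values stayed within bounds, 20 moved further and 6 counts of 0 became larger. The bounds were 1.5 times for a count and 0.0534 for the correlation, the SD of its leave-one-out values. The 57 include counts of 0 that stayed 0, to which a bound of 1.5 times does not apply. Among values of the 4 named genes, 149 kept their side of the threshold, 18 lost it and 3 gained it, and 0 changed direction past it. RLE scaling and no filter changed none of the 5 results by over 1.5 times.

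DESeq2 gave 476 genes in ICH_MA against ICH, 377 reversed genes and 1823 genes in ICH_MA against sham. Simulated false calls were more frequent with it, in counts drawn with edgeR's own estimates of spread. For ICH_MA against sham, limma-voom gave 2104 (61% higher) and the model of only these groups 1541. The added fold threshold gave 802 in ICH against sham and 334 in ICH_MA against sham, by its construction. DESeq2 without ICH replicate 5 gave 2013 in ICH_MA against ICH, 1795 reversed genes and 2261 in ICH_MA against sham.

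With the replicate block, ICH against sham gave 1914 genes (74.5% higher), ICH_MA against sham 117 (97.4% higher), and ICH_MA against ICH and the reversed genes 0. In ICH against sham, ENSRNOG00000065254 then had a log2 fold change of 12.31 (edgeR adjusted p = 0.0707), against 10.95 without the block. With 0 counts in sham its fitted fold depends on the prior count. ENSRNOG00000017302 had a log2 fold change of −2.87 with the block. Same-numbered libraries did not deviate together (8 pairs, correlations −0.16 to 0.09), and 0 of 10 libraries correlated best with their own number, so the numbers were not taken to pair rats.

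With 1 library of the groups compared left out, ICH against sham ranged from 1992 (without ICH replicate 1) to 4484 (without ICH replicate 5), with 2231 without ICH replicate 2. ICH_MA against sham ranged from 348 (without ICH_MA replicate 2) to 1338 (without Sham replicate 1, 59.6% higher), with 545 to 577 without another sham library, and 459 and 506 without ICH_MA replicates 1 and 3. It was 1575 without ICH replicate 5, outside its groups. ICH_MA against ICH ranged from 0 to 1137 and reversed genes from 0 to 1067, both highest without ICH replicate 5. The correlation of fold changes ranged from −0.765 (without ICH replicate 5) to −0.561 (without ICH_MA replicate 3), and was −0.593 without ICH_MA replicate 2. Except where stated, the cause was not tested.

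Not run were the alternatives for cuproptosis genes and gene lists, whose symbols could not be matched. Depth was similar between groups. Recovery of 1.5-fold changes was 46% to 62% in simulated data, so small changes can be missed.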

Other observations

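The count of 1137 genes called in ICH_MA against ICH without ICH replicate 5 was examined after it was seen. Of these genes, 1067 ran opposite to a call in ICH against sham from the same libraries, 2 ran in the same direction and 68 were not called there. Of those 68, 63 had a fold change opposite to that of ICH against sham. Only 3 of the 1137 were also called against sham in the direction opposite to the change with hemorrhage. DESeq2 on all libraries shared 354 of them. Both comparisons use the same 2 ICH libraries, so opposite directions are favoured by chance.

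Genes near 0 in sham were few among the genes kept by the filter. The table itself held few low genes, as 14618 of 15094 had at least 10 counts in every library. Any filter before it is not given. How many silent genes hemorrhage switched on cannot be told from these counts. At most 3 counts in every sham library were seen for 8 genes, of which 2 had at least 10 counts in every ICH library. Of these 2, 0 had at least 10 counts in every ICH_MA library and 0 had them in no ICH_MA library, so both stayed detected in some. No gene (0) had at most 3 counts in every ICH library and at least 10 in every sham library.

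The first principal component of log2 CPM took 45.7% of the variance and placed sham at −35.7 to −26.9, ICH replicates 1, 2 and 5 at 57.2, 48.8 and 13.3, and ICH_MA at 6.5 to 20.3. The second took 10.4%.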
